A study of Homo sapiens with 12 samples.

How the data were processed

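RNA was sequenced from LMSU, a human gastric cancer cell line that carries the p53 variant R175H according to the labels. The 12 libraries form 6 groups of 2. In the knockout arm, labelled without doxycycline, a control construct (V2) was compared with a knockout construct (sg-1), both marked GFP. In the knockdown arm, labelled with doxycycline, hairpins against p53 (shRNA 1 and shRNA 2) were compared with a scramble hairpin and with vector. Per the labels, cells were grown in Ham's F-10 medium and libraries were made from total RNA with an mRNA library kit. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so each n of 2 counts libraries.

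The authors deposited 1 table of raw read counts per gene symbol, with 1 column per library and no normalisation. Their processing notes list bcl2fastq, STAR 2.5 and the hg19 build. The counting mode, the strand setting and the annotation are not given in the sources used here. Reads from genes that overlap on opposite strands may therefore be shared between them. The table held 25435 symbols, and library totals ran from 9738094 to 16823246 counts. All values in the table were whole numbers.

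Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr (minimum count 10), which left 13365 genes, and library sizes were scaled with TMM. Levels are given as TMM-normalised CPM, as mean ± SD with n = 2. The 6 groups were fitted together with 1 coefficient each (6 residual degrees of freedom), and contrasts were tested with the quasi-likelihood F test of edgeR, which is two-sided. P values were adjusted by Benjamini-Hochberg over the 13365 genes within each comparison, and a gene was called at an adjusted p below 0.05. The comparisons were knockout against its control, each hairpin and the mean of both hairpins against scramble, shRNA 1 against shRNA 2, scramble against vector, and the knockout effect minus the knockdown effect. The knockdown comparisons were also made against vector. Genes called the same way in the knockout and with both hairpins were counted.

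Genes were named in the text by a rule: CDKN1A and MDM2 always, and otherwise the called genes with the largest log2 fold change whose libraries did not overlap between the sides compared and whose mean reached 5 CPM on the higher side. For the knockout effect minus the knockdown effect, overlap was not checked, and the 5 CPM had to be reached in any group only. The rule took 8 in each direction for the knockout and the mean knockdown and 3 in each direction for the other comparisons, and left out clone, antisense, pseudogene and small RNA names. Some genes that the rule picked are not reported here. From each gene list described, up to 4 members with the smallest adjusted p were named. In total 40 gene lists were written from general knowledge, and 873 of their 888 entries were matched to the table, 36 of them through an older symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists with enough tested members, and again with an estimated correlation. The mitochondrially encoded genes had 0 tested members, and the gastric and the intestinal lineage genes had 2 each, so these lists were not run. The design, the lists, the naming rule and most of the alternative settings were fixed before the data were examined.

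The procedure was tested on simulated data in which 200 of the 13365 genes were changed. In the knockdown comparison the fit to all libraries recovered 40.3%, 85.1% and 95.5% of the genes changed by 1.5-fold, 2-fold and 4-fold, with 0 false calls. In the knockout comparison it recovered 44.8%, 83.6% and 97.0%, but made 435 false calls, with a pooled spread smaller than that simulated for the knockout arm. The simulation drew each gene on its own. The same fit called 2 genes in the real knockout comparison, so the 435 are no estimate of its false calls. A fit to the compared knockout libraries alone recovered 2.99%, 37.3% and 89.4% with 1 false call.

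Alternatives were DESeq2 1.42.0, limma-voom, other size factors, no filter and a stricter filter, the compared libraries alone, a replicate block, a stricter threshold, a fold limit, vector or the mean of both controls as control, and each library left out in turn. Added after the data had been seen were a crossed replicate block and a block in the knockout arm alone, a fit to the 8 knockdown-arm libraries, counts thinned to the lowest total, list tests with the compared libraries only, and the set of genes called with both hairpins against both controls. Correlations across genes between comparisons that share a control were set beside 100 simulations of groups with no effect. Figures were drawn with matplotlib 3.10.9.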

Results

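Gene expression was measured by RNA sequencing in 12 libraries of the LMSU gastric cancer line, in 6 groups of 2: knockout control, p53 knockout, scramble hairpin, p53 shRNA 1, p53 shRNA 2 and vector. Total counts were 13666562 and 10351171 in the knockout control, 11998608 and 13538425 in the knockout, 12971347 and 13873470 in scramble, 11500899 and 9738094 with shRNA 1, 13106727 and 14001411 with shRNA 2, and 13836692 and 16823246 in vector. The biological coefficient of variation was 15.6% in the knockout arm and 3.08% in the knockdown arm, and 9.55% over all 12 libraries. In every group the 2 libraries differed by more than sampling noise.

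Textbook targets of p53 were called singly and not as a list. CDKN1A, which encodes the cell cycle inhibitor p21, was at 117 ± 1.91 CPM in scramble, 87.1 ± 4.41 CPM with shRNA 1 and 199.7 ± 10.6 CPM with shRNA 2. It fell by 0.43 on the log2 scale with shRNA 1 (SE 0.12, adjusted p 0.041) and rose by 0.77 with shRNA 2 (SE 0.11, adjusted p 0.0024), while vector stood at 69.2 ± 1.13 CPM. Against vector CDKN1A was at 0.33 with shRNA 1 (adjusted p 0.088) and 1.53 with shRNA 2 (adjusted p 6.6e-06), and in the knockout it was at -0.20 (adjusted p 0.78). MDM2, which encodes the ubiquitin ligase of p53, had log2 fold changes of 0.20 in the knockout (adjusted p 0.79), -0.07 with shRNA 1 (adjusted p 0.85) and -0.13 with shRNA 2 (adjusted p 0.72). Of 29 tested p53 target genes, 0 were called in the knockout and 3 in the mean knockdown, among them SESN2, which rose by 0.44, and PLK2, which fell by 0.29; adjusted over the list alone, 0 and 4 were called. The list medians were -0.05 (camera adjusted p 0.75) and 0.05 (camera adjusted p 0.61).

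**Figure D1:**
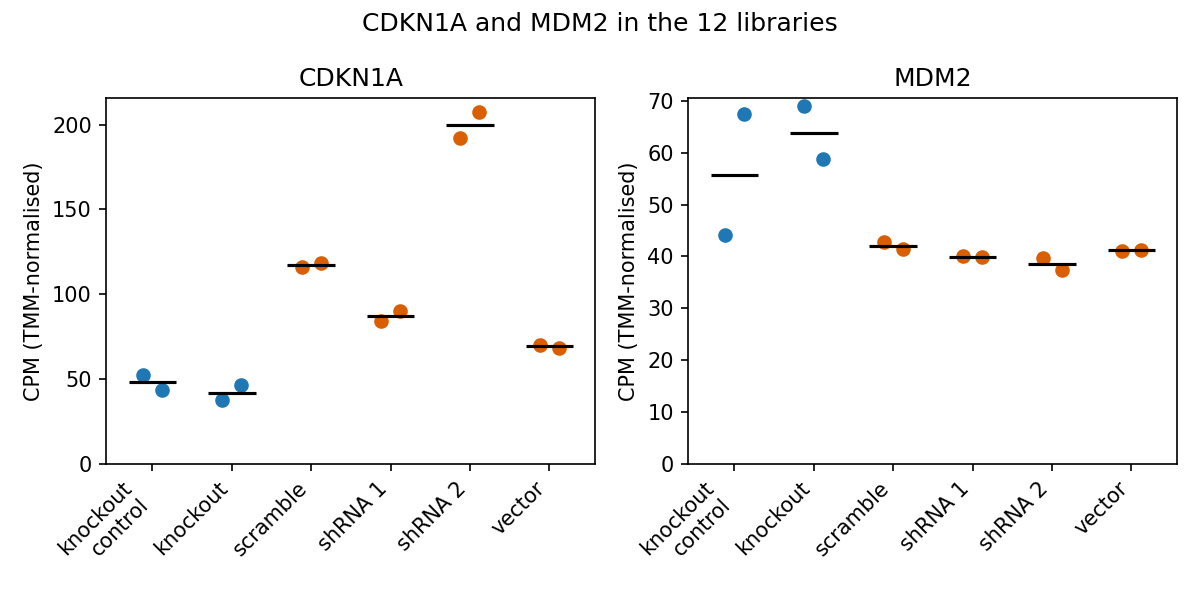
Levels of CDKN1A and MDM2 in TMM-normalised CPM in each of the 12 libraries (points) with the group mean (line), for the knockout arm in blue and the knockdown arm in orange. CDKN1A is lowest of the hairpin groups with shRNA 1 at 87.1 CPM and highest with shRNA 2 at 199.7 CPM.

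The knockout comparison asks what changes with the construct that targets p53. DCN, the gene of the matrix proteoglycan decorin, was called: it rose by 0.69 on the log2 scale (SE 0.087, edgeR adjusted p 0.038), with both knockout libraries above both control libraries. Against scramble DCN was at -0.08 with shRNA 1 (adjusted p 0.60) and 0.87 with shRNA 2 (adjusted p 1.3e-04), and against vector at 2.14 and 3.09. It was also 2.22 higher in scramble than in vector, which both keep p53 according to the labels. Fibroblast markers, a list of matrix and stromal genes, had a median log2 fold change of 0.35 over 13 tested members. LUM (0.56, adjusted p 0.068), COL3A1 (0.35, adjusted p 0.28) and POSTN (1.41, adjusted p 0.23), which encode the matrix proteins lumican, collagen III and periostin, lay in the same direction without passing the test. Adjusted over the list alone, 9 of the 13 were called, and camera gave an adjusted p of 6.0e-16 (adjusted p = 0.0038 with an estimated correlation). Mesenchymal genes (median 0.11), which share members with the fibroblast list, and TGF-beta target genes (median 0.08) each had a camera adjusted p of 0.0018, and for both adjusted p = 0.088 with an estimated correlation. Adjusted over the list alone, 5 mesenchymal genes and 1 TGF-beta target gene, THBS1 (0.47), were called. The calls over the list alone, those of the fibroblast markers included, use the pooled fit. Its biological coefficient of variation, 9.55%, lies below the 15.6% of the knockout arm.

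G2/M and mitosis genes had a median of 0.11 in the knockout (camera adjusted p 0.038; adjusted p = 0.21 with an estimated correlation). Glycolysis genes had a median of -0.18 (camera adjusted p 3.4e-04; adjusted p = 0.77 with an estimated correlation) and ribosomal protein genes a median of -0.15 (camera adjusted p 0.0018; adjusted p = 0.81 with an estimated correlation). The ribosomal list also differed between the 2 control libraries, by a median of 0.65, and without replicate 1 of the control the glycolysis and ribosomal medians became 0.024 and 0.20. Adjusted over the list alone, 0 members of these 3 lists were called.

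In all, 2 genes were called in the knockout, DCN among them, and 859 of 13365 had an unadjusted p below 0.05. The fit to the 4 compared libraries called 0 genes and DESeq2 called 21, so DCN rests on the pooled spread. In simulated data the pooled fit made 435 false calls here. That simulation does not match the real libraries, where the pooled fit called 2 genes in all. The count depended on the libraries kept: it rose when either library of the knockout control was left out, and by far the most without replicate 2. The labels state no pairing of the libraries, and a crossed block that paired replicate 1 of the knockout with replicate 2 of its control, and the reverse, chosen after the data had been seen, called 624.

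The knockdown comparison asks what changes with hairpins against p53, in libraries labelled with doxycycline. Against scramble the largest increases included MIR210HG, the host transcript of a hypoxia-induced microRNA (1.72, SE 0.19, adjusted p 4.9e-04), P4HA1, a collagen prolyl hydroxylase gene (1.58, SE 0.077, adjusted p 1.5e-06), and BNIP3L, a mitophagy receptor gene (1.5, SE 0.088, adjusted p 6.3e-06). The other genes with the largest increases were ELFN1 (1.41), AK4 (1.39), LRRC20 (1.38), ICK (1.34) and EPYC (1.32). Among the largest decreases were IL24, a cytokine gene (-1.49, SE 0.11, adjusted p 2.7e-05), C14orf37 (-1.38), CEMIP, which encodes a hyaluronan-binding protein (-1.37), FAIM3 (-1.30), WDR66 (-1.22), TTC29 (-1.17) and ELOVL4, a fatty acid elongase gene (-1.16). These values are means of both hairpins over scramble, and in each case the 4 hairpin libraries lay on 1 side of the 2 scramble libraries. Against vector, ELFN1 (0.98), EPYC (1.73), C14orf37 (-0.79) and WDR66 (-0.47) were called in the same direction. MIR210HG (-0.66), P4HA1 (-0.32), IL24 (1.07) and TTC29 (1.08) were called in the opposite direction, and BNIP3L (-0.11), AK4 (0.07), LRRC20 (0.09), ICK (0.08), CEMIP (-0.07), FAIM3 (0.55) and ELOVL4 (-0.48) were not called. Of the genes not called, CEMIP was called singly with both hairpins, in opposite directions (-0.84 with shRNA 1 and 0.71 with shRNA 2). FAIM3 (1.18) and ELOVL4 (-0.91) were called with shRNA 2 only. Against scramble, EPYC was not called with shRNA 1 (0.55), nor FAIM3 with shRNA 2 (-0.66).

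Of 20 tested hypoxia genes, 12 rose and 0 fell against scramble, with a median of 0.49 (camera adjusted p 2.0e-24; adjusted p = 9.5e-04 with an estimated correlation), and BNIP3 (0.88) and NDRG1 (0.60) were among them. Adjusted over the list alone, 14 rose and 1 fell. Of 18 glycolysis genes, 6 rose, among them ENO2 (0.89), PGK1 (0.73), LDHA (0.50) and PGAM1 (0.42), with a median of 0.28 (camera adjusted p 1.1e-09; adjusted p = 0.32 with an estimated correlation) and 12 adjusted over the list alone. Against vector both lists lay the other way: the hypoxia median was -0.30, with 1 gene up and 9 down (camera adjusted p 0.0012; adjusted p = 0.0497 with an estimated correlation), and the glycolysis median was -0.42, with 13 down (camera adjusted p 5.9e-09; adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone against vector, 1 hypoxia gene was up and 11 were down, and 14 glycolysis genes were down.

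NF-kB targets and chemokines had a median of -0.33 against scramble, with 1 of 22 up and 6 down, among them TRAF1 (-1.70), IL1A (-1.09), ICAM1 (-0.47) and SOD2 (-0.42), and 1 up and 12 down adjusted over the list alone (camera adjusted p 8.8e-09; adjusted p = 0.10 with an estimated correlation). Against vector the median was 0.95, with 18 up and 0 down and 19 up adjusted over the list alone (camera adjusted p 2.0e-28; adjusted p = 0.0052 with an estimated correlation). ER chaperone genes fell in 5 of 20, HYOU1 by 0.53, PDIA4 by 0.43, HSPA5 by 0.41 and HSP90B1 by 0.37, and in 9 adjusted over the list alone, with a median of -0.22 (camera adjusted p 6.4e-06; adjusted p = 0.21 with an estimated correlation). Antigen presentation genes fell in 3 of 17, ERAP2 by 0.55, PDIA3 by 0.25 and TAPBP by 0.23, and in 4 adjusted over the list alone, with a median of -0.22 (camera adjusted p 3.9e-04; adjusted p = 0.47 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 23, among them SQLE by 0.67, CYP51A1 by 0.49 and DHCR7 by 0.45, and in 9 adjusted over the list alone, with a median of -0.20 (camera adjusted p 9.3e-04; adjusted p = 0.10 with an estimated correlation). Against vector these 3 cholesterol genes were also lower and called, at -0.22 for SQLE, -0.32 for CYP51A1 and -0.46 for DHCR7. As lists, cholesterol synthesis (median -0.057), antigen presentation (0.10) and ER chaperone genes (median 0.023, mean -0.015) were not called against vector, with camera adjusted p of 0.72, 0.34 and 0.74. Fibroblast markers had 3 of 13 up against scramble (median -0.0058, camera adjusted p 0.38; 4 up and 2 down adjusted over the list alone) and 9 up against vector (median 0.56, camera adjusted p 1.6e-18; adjusted p = 0.0013 with an estimated correlation; 9 up and 1 down adjusted over the list alone).

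Cell cycle lists had small medians against scramble. G1/S and replication genes rose in 4 of 24, E2F2 by 1.38, POLE2 by 0.77, CLSPN by 0.54 and MCM4 by 0.24, and in 9 adjusted over the list alone, with a median of 0.19 (camera adjusted p 7.3e-04; adjusted p = 0.19 with an estimated correlation). Nucleotide synthesis genes rose in 5 of 20, among them RRM1 (0.90), PRPS2 (0.55), RRM2 (0.49) and PAICS (0.37), with a median of 0.08 (camera adjusted p 0.0050; adjusted p = 0.30 with an estimated correlation) and 5 up and 1 down adjusted over the list alone. DNA repair genes had a median of 0.16 with 1 of 26 up, and 2 adjusted over the list alone (camera adjusted p 0.036; adjusted p = 0.51 with an estimated correlation). G2/M and mitosis genes had a median of -0.15 with 0 of 24 called, and 0 adjusted over the list alone (camera adjusted p 0.020; adjusted p = 0.19 with an estimated correlation). Against vector the nucleotide synthesis median was -0.15 with 4 down, and 4 adjusted over the list alone (camera adjusted p 0.026; adjusted p = 0.28 with an estimated correlation), and the DNA repair median was -0.37 with 6 down, and 9 adjusted over the list alone (camera adjusted p 0.017; adjusted p = 0.34 with an estimated correlation). Against vector the G1/S median was -0.41 (camera adjusted p 3.8e-04; adjusted p = 0.11 with an estimated correlation). Against vector the G2/M median was -0.84 with 22 of 24 down, among them AURKA (-1.08) and PLK1 (-1.08), and 23 adjusted over the list alone (camera adjusted p 3.5e-32; adjusted p = 3.8e-04 with an estimated correlation).

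**Figure D2:**
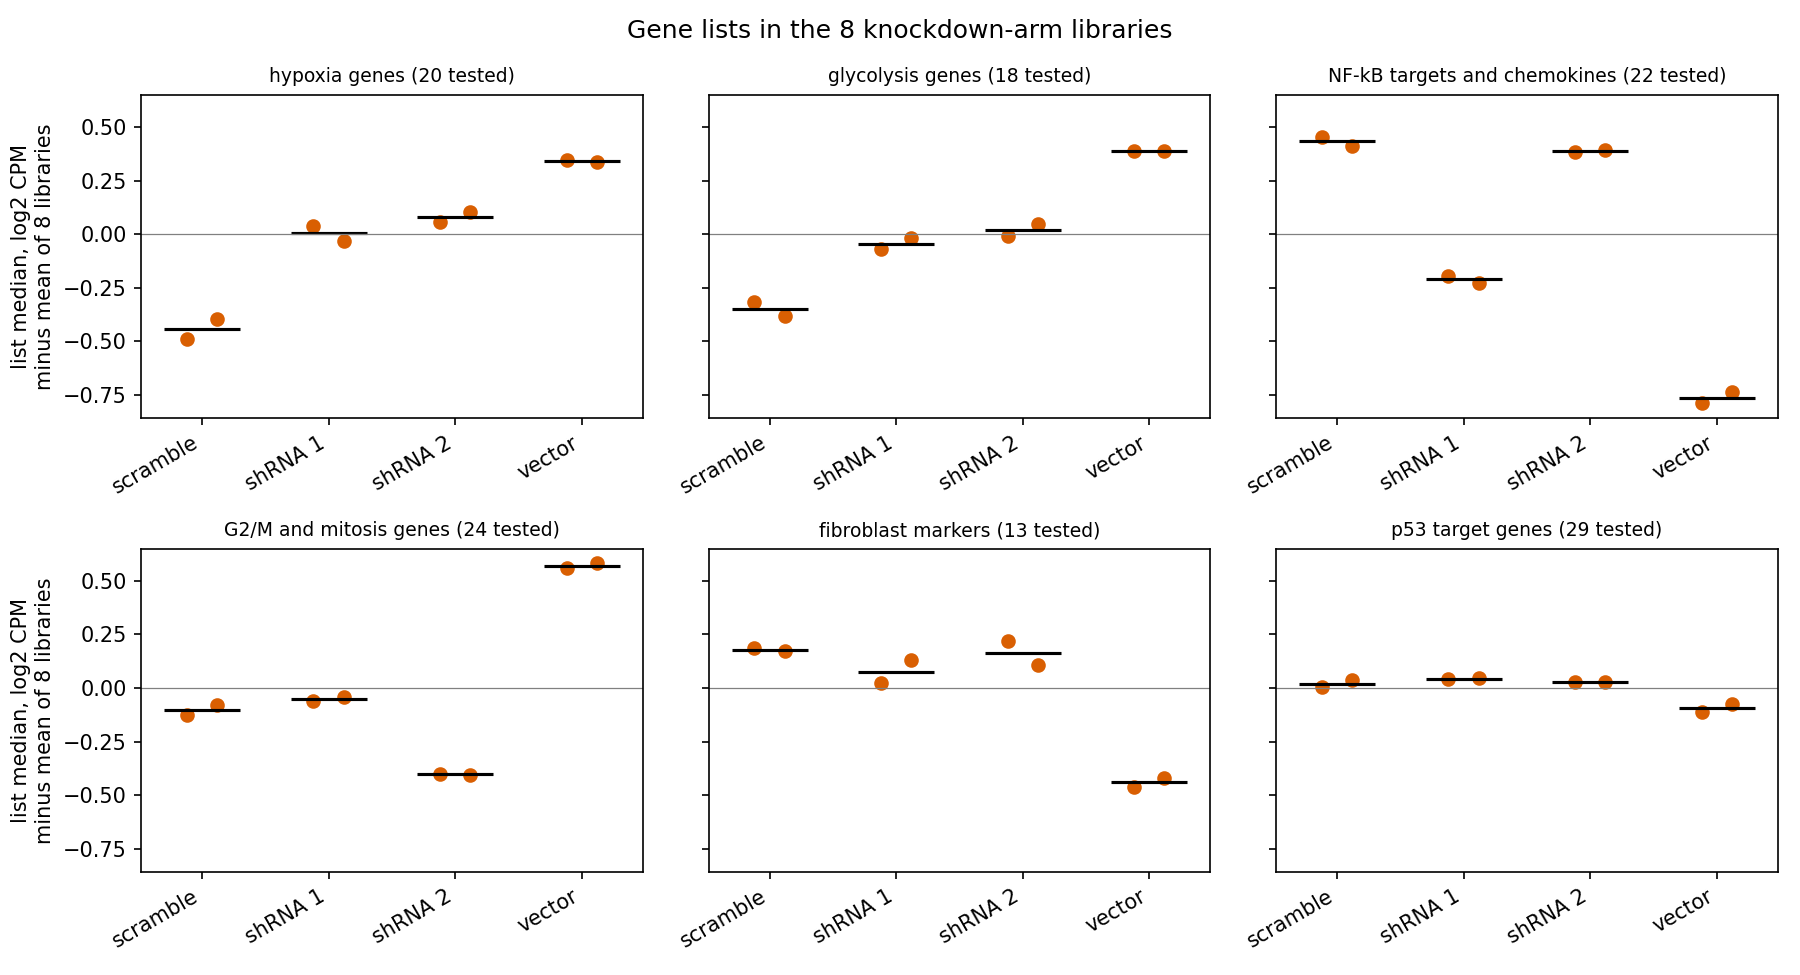
Median over each list of the log2 CPM of its members minus their mean over the 8 knockdown-arm libraries, for each library (points) with the group mean (line). In the hypoxia and glycolysis panels the hairpin libraries lie between scramble and vector, while the p53 target panel spans -0.11 to 0.05.

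In all, 905 genes were called in the mean knockdown, 416 up and 489 down, and 77 of them changed by at least 2-fold. Of the 905, 320 were called in the same direction against vector, 129 in the opposite direction, and 456 were not called. A fit to the 8 knockdown-arm libraries called 3872 genes, and the count fell to 134 and 135 without a scramble library and to between 439 and 481 without any of the hairpin libraries.

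The genes called with both hairpins against both controls numbered 70, a set defined after the data had been seen, with 31 up and 39 down. Among those that rose were CSF2RB, a cytokine receptor gene (1.01 with shRNA 1 and 0.96 with shRNA 2 against scramble), TRPV1, an ion channel gene (0.91 and 0.92), TXNIP, which encodes a thioredoxin-binding protein (0.58 and 0.96), KLF10, a TGF-beta-induced transcription factor gene (0.58 and 0.77), and DGCR8, a gene of microRNA processing (0.53 and 0.61). FAM198B, SS18L1 and MMD also rose. Among those that fell were RGS4, a regulator of G protein signalling (-1.02 and -1.09), THY1, a cell surface glycoprotein gene (-0.75 and -0.97), STC2, the stanniocalcin 2 gene (-0.64 and -0.78), and CLU, the clusterin gene (-0.74 and -1.43). ELMO1 and ITPK1 also fell. The largest adjusted p over the 4 tests was 0.0059 for CSF2RB, 0.012 for TRPV1, 8.9e-04 for TXNIP and 0.0059 for RGS4. In the fit to the 8 knockdown-arm libraries the set numbered 535 genes and held all 70. That fit reuses the same libraries with a smaller spread, so it is no independent support for the 70.

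**Figure D3:**
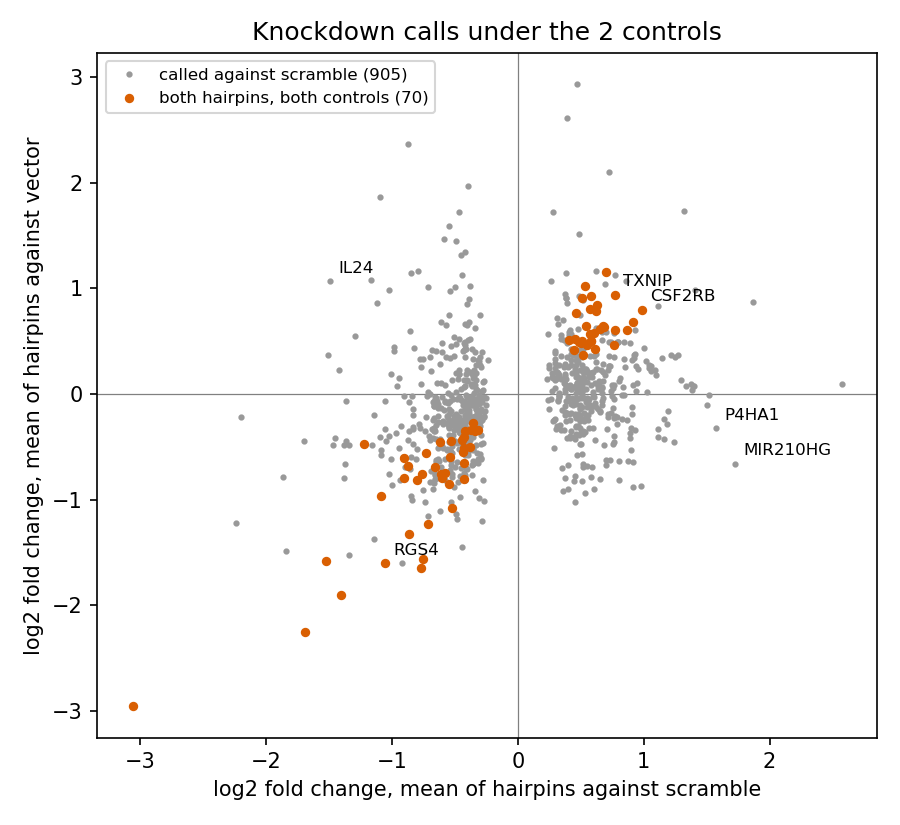
Each point is 1 of the 905 genes called in the mean knockdown against scramble, with its log2 fold change against scramble on the horizontal axis and against vector on the vertical axis, and the 70 genes called with both hairpins against both controls are in orange. P4HA1 (1.58 and -0.32) and IL24 (-1.49 and 1.07) change sign with the control.

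The hairpins were also compared with scramble singly. MIR210HG (1.78), MEST, an imprinted gene (1.68), and DMBT1, a mucin-like glycoprotein gene (1.60), rose most with shRNA 1, and among the largest decreases were IL24 (-2.22) and CEMIP (-2.14). With shRNA 1, 14 of 22 NF-kB targets fell and 0 rose (median -0.53, camera adjusted p 1.9e-20; adjusted p = 0.016 with an estimated correlation; 17 down adjusted over the list alone). EPYC (2.09), ELFN1 (1.81) and ADAMTS4, a proteoglycan-cleaving protease gene (1.69), rose most with shRNA 2, and among the largest decreases were C14orf37 (-1.66) and ELOVL4 (-1.58). With shRNA 2, 7 of 24 G2/M genes fell (median -0.32, camera adjusted p 1.7e-06; adjusted p = 0.020 with an estimated correlation; 12 down adjusted over the list alone). The hypoxia median was 0.42 with shRNA 1 and 0.65 with shRNA 2, with camera adjusted p 3.4e-12 and 4.7e-24 (adjusted p = 0.0073 and adjusted p = 9.9e-04 with an estimated correlation; 10 up, and 13 up and 1 down, adjusted over the list alone). Against vector it was -0.36 with shRNA 1 and -0.29 with shRNA 2, with camera adjusted p 1.6e-05 (adjusted p = 0.027 with an estimated correlation) and 0.11. In all, 1258 genes were called with shRNA 1 (588 up, 670 down) and 1034 with shRNA 2 (479 up, 555 down). Against vector, MEST (0.58) and IL24 (0.34) were not called with shRNA 1 and MIR210HG was at -0.60, and the counts were 1742 and 2801. Without 1 of the scramble or hairpin libraries the counts were 340 to 397 and 235 to 275.

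Both hairpins raised 171 genes and lowered 123 against scramble, where independent lists would share 21.1 and 27.8. The comparisons share the scramble libraries: the correlation of their log2 fold changes across genes was 0.38, while simulated groups with no effect gave 0.47, and their covariance was 0.067, against 0.017 in the simulation. With vector as the shared control the correlation was 0.57 and the covariance 0.14, beside the same simulated values of 0.47 and 0.017, and both hairpins raised 408 genes and lowered 539. With shRNA 1 against scramble and shRNA 2 against vector, which share no library, the correlation was -0.17, and with the controls exchanged it was 0.042. Scramble and vector differed in 2039 genes, and that difference also enters these 2 values. They therefore do not measure the agreement of the hairpins alone. The simulation gave all groups the same means and the replicate spread alone. A shift of the shared control apart from p53 would therefore also raise the covariance above the simulated value. Genes are not independent replicates, so these values describe the profiles and carry no p value.

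The hairpins were compared with each other to see how far they act alike. DMBT1 (2.20), PSAT1, a serine synthesis gene (1.92, SE 0.13, adjusted p 2.1e-05), and MATN2, a matrix protein gene (1.80), were higher with shRNA 1. SERPINB2, an inhibitor of plasminogen activators (-2.74, SE 0.16, adjusted p 8.6e-06), and ADAMTS4 (-1.85) were lower with shRNA 1. NF-kB targets were lower with shRNA 1 in 14 of 22 and higher in 0, CXCL8 at -1.41, IL1B at -1.46, IL1A at -1.19 and SOD2 at -1.09 (median -0.57, camera adjusted p 1.0e-16; adjusted p = 0.030 with an estimated correlation; 15 adjusted over the list alone). G2/M genes were higher with shRNA 1 in 9 of 24, among them HMMR (0.69) and CCNB2 (0.60) (median 0.36, camera adjusted p 1.2e-05; adjusted p = 0.030 with an estimated correlation; 11 adjusted over the list alone). In all, 1909 genes differed, 945 higher and 964 lower with shRNA 1, and without 1 of the 4 libraries the count was 682 to 799.

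Scramble and vector both keep p53 according to the labels, although the vector construct is not described in the sources used here. They differed in more genes than either hairpin differed from scramble. GPR84, a fatty acid receptor gene (3.57), MMP9, a matrix metalloprotease gene (3.23, SE 0.23, adjusted p 8.0e-06), and MYBPH (3.22) were higher in scramble, and PRELP (-2.69), APLN, the apelin gene (-2.66), and MIR210HG (-2.38) were lower. NF-kB targets were higher in scramble in 21 of 22, IL1A by 2.95, IL1B by 2.80, CXCL8 by 2.04 and SOD2 by 1.76 (median 1.26, camera adjusted p 3.1e-47; adjusted p = 0.0011 with an estimated correlation; 21 adjusted over the list alone). Hypoxia genes were lower in 15 of 20 and higher in 1, P4HA1 at -1.90, BNIP3L at -1.61 and BNIP3 at -1.51 (median -0.80, camera adjusted p 3.2e-23; adjusted p = 0.0011 with an estimated correlation; 18 lower adjusted over the list alone). Glycolysis genes were lower in 15 of 18 (median -0.69, camera adjusted p 8.6e-22; adjusted p = 0.071 with an estimated correlation; 17 adjusted over the list alone), and PGK1 was at -1.35. G2/M genes were lower in 21 of 24, BIRC5 at -1.31 and FOXM1 at -0.89, and G1/S genes in 18 of 24, CDT1 at -1.20 (medians -0.67 and -0.66, camera adjusted p 2.0e-18 and 5.4e-09; adjusted p = 0.0011 and adjusted p = 0.029 with an estimated correlation; 23 and 19 adjusted over the list alone). Fibroblast markers were higher in 7 of 13, DCN by 2.22 and LUM by 1.44 (median 0.58, camera adjusted p 8.3e-15; adjusted p = 0.0014 with an estimated correlation; 8 adjusted over the list alone). In all, 2039 genes differed, 949 higher and 1090 lower in scramble, and without 1 of the 4 libraries the count was 879 to 921. Of the 905 knockdown calls, 460 also differed between the controls, 414 of them with the sign opposite to the knockdown effect. The 2 comparisons share the scramble libraries with opposite sign, so opposite signs are expected with no effect: the correlation across genes was -0.48, and simulated groups with no effect gave -0.58. The covariance was larger in size, -0.083 against -0.017 in that simulation, which holds replicate spread alone. What brings the excess was not tested.

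The knockout and knockdown effects were compared by a test of their difference. CAMK1G, a calcium-dependent kinase gene (2.32, SE 0.46, adjusted p 0.039), ITM2A (2.01, SE 0.29, adjusted p 0.0090) and GALNT3, a glycosyltransferase gene (1.80, SE 0.27, adjusted p 0.012), had the higher effect in the knockout. Against vector these differences were 1.22 for CAMK1G (adjusted p 0.25), 2.11 for ITM2A (adjusted p 0.0018) and 0.81 for GALNT3 (adjusted p 0.14). Levels in the knockout arm were low: CAMK1G was at 0.27 CPM in the knockout control and 0.71 CPM in the knockout, and ITM2A at 0.89 and 2.27 CPM. MIR210HG (-2.09), PPFIA4 (-1.81) and BNIP3L (-1.46) had the lower effect, and against vector these 3 differences were 0.29, 0.033 and 0.14. Of 20 hypoxia genes 5 had the lower effect in the knockout (median -0.51, camera adjusted p 6.4e-21; adjusted p = 0.0015 with an estimated correlation; 12 adjusted over the list alone). Against vector the hypoxia list lay the other way, with 4 genes higher and 1 lower (median 0.25, camera adjusted p 0.017; adjusted p = 0.12 with an estimated correlation; 5 higher and 1 lower adjusted over the list alone). In all, 147 genes differed, 86 higher and 61 lower, and 1 gene was called the same way in the knockout and with both hairpins. The difference depends on single libraries: 3342 genes were called without replicate 2 of the knockout control, 705 without replicate 1 of it, 1951 with the crossed block, and 25 to 54 without any other of the compared libraries. Doxycycline and the arm coincide in all libraries, so neither can be separated from the way p53 was removed. The correlation across genes of the knockout and the knockdown effect was 0.0076 against scramble and 0.10 against vector.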

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

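Vector as control, the libraries left out and the tests of differences were planned, and thinning was chosen before its result was seen. The question of hairpin off-target effects rests on no result, and the other tests of explanations, the use of a left-out library among them, were chosen after the values they use had been seen.

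Hypoxia, glycolysis and NF-kB lists change direction in the mean knockdown with the choice of control, as in the hypoxia median of 0.49 against scramble and -0.30 against vector. For NF-kB the fall against scramble lay mainly with shRNA 1, while the list levels of shRNA 2 lay near those of scramble. After thinning to the lowest total the hypoxia list stayed called between scramble and vector (camera adjusted p 2.6e-23), so that call does not need unequal depth. Its median stayed at -0.80, which decides nothing further, since thinning keeps the expected ratios of well-counted genes. For the state of the cultures at collection, the bound set for its exclusion was met, as the 2 libraries of the knockout control differed by a hypoxia median of 0.076 and a glycolysis median of 0.36, both inside the range of matched random lists, -0.14 to 0.32 and -0.083 to 0.38, and so did the knockout libraries; that bound was badly chosen, because libraries of 1 group can share a state, and it decides nothing. Culture state, construct and a p53 effect added to a difference between the controls cannot be told apart, since each group holds 1 construct.

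Few genes were called in the knockout (2) and many in the knockdown (905). The effects themselves differed in 147 genes with the pooled spread, and in 53 with the compared libraries only. The same effect hidden by the spread of the knockout libraries is argued against for 69 genes, taken as a set. They are 69 of the 70 called with both hairpins against both controls. Their signed median was 0.60 in the knockdown and at most 0.081 in the 4 pairs of knockout and control libraries. These genes were picked for their knockdown calls, which can inflate the 0.60, and the pairs reuse the same libraries. Singly, 22 of the 69 were called in the test of the difference. The knockout median was 0.11 for the 31 raised genes and 0.01 for the 38 lowered ones. The other knockdown calls stay open. One control library that stands apart stays open: 17 genes were called without replicate 1 of the knockout control, and far more without replicate 2. The 17 met the bound set for its exclusion, on the full knockdown count of 905. That bound decides nothing, since without replicate 1 the control is a lone library whose spread is assumed. Knockdown counts with a lone scramble library depend on whether the hairpins are pooled, so they give no fixed value to set beside the 17. A pairing of the libraries across replicate numbers stays open, since the labels state none and a block of that kind called 624 genes. Residual p53 protein, which counts of RNA cannot show, may contribute and was not tested, and the arm and doxycycline differ together with the way p53 was removed and stay open, untested.

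The hairpins differed from each other in 1909 genes, more than either differed from scramble. Against vector 1742 genes were called with shRNA 1 and 2801 with shRNA 2, so this does not hold for shRNA 2 there. A single effect that differs between the hairpins in strength alone stays open. The root mean square log2 difference was 0.35 between the hairpins, above those of shRNA 1 (0.31) and shRNA 2 (0.29) to scramble. With scramble as the zero point, strength alone would not let it exceed the larger of these. The distances to vector were 0.354 for shRNA 1 and 0.435 for shRNA 2, both above the 0.348 between the hairpins. With vector as the zero point that limit is not exceeded. All these distances carry no spread, and scramble may have a shift of its own, as it lay 0.39 from vector. Of the differing genes 44.4% had opposite signs with the 2 hairpins against both controls. These signs were counted without a threshold in genes picked for differing. With the threshold, 70 genes were called in the same direction with both hairpins against both controls and 5 in opposite directions. The 70 do not decide it, since the shared control libraries favour the same direction with no effect (simulated correlation 0.47). That sharing does not favour the 5, but they are too few to speak for the 1909. Among the 5 were ADAM12, EFEMP1, DIXDC1 and TSPAN13, named after their values were seen. Whether the hairpins part along the axis that parts the controls was not decided: the correlation across genes of shRNA 1 minus shRNA 2 with scramble minus vector, which share no library, was -0.20, between the bounds set, and of 639 genes called in both, where independent lists would share 291, 521 had opposite signs and 118 the same sign. Off-target effects may contribute, and 615 genes were called with a hairpin against both controls, not the same way with the other, and differed between the hairpins, but hairpin sequences were not used here, and hairpin sequence and culture cannot be told apart with 1 group per hairpin.

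The following single genes differed by the test of the difference itself, given as log2 values. The knockout effect exceeded the knockdown effect by 2.32 for CAMK1G, 2.01 for ITM2A and 1.80 for GALNT3, and against vector by 1.22, 2.11 and 0.81, of which the values for CAMK1G and GALNT3 were not called. The knockout effect minus the knockdown effect was -2.09 for MIR210HG, -1.81 for PPFIA4 and -1.46 for BNIP3L, and against vector 0.29, 0.033 and 0.14. Between the hairpins, DMBT1 was higher with shRNA 1 by 2.20, PSAT1 by 1.92 and MATN2 by 1.80. The value for shRNA 1 minus shRNA 2 was -2.74 for SERPINB2, -1.85 for ADAMTS4 and -1.20 for CDKN1A.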

How the results depend on the processing

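The crossed replicate block, the block in the knockout arm alone, the fit to the 8 knockdown-arm libraries, thinning, the list tests with the compared libraries only and the set over both controls were chosen after the data had been seen; the other alternatives were planned. Of the values recomputed for counts and correlations, 68 stayed within their bounds, 87 moved and 1 reversed; of those for single genes and lists, 1619 kept direction and side of the threshold, 181 kept direction but no longer passed, 6 newly passed, 35 reversed and 1 moved. With 2 libraries per group, leaving 1 out makes the other a lone sample, assumed to vary like the other groups. Where a cause is not named below, the cause was not tested.

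The knockout count of 2 was 21 with DESeq2, 1 with limma-voom, 64 with no filter, 0 with the compared libraries alone, 1 with the replicate block, 1 at an adjusted p below 0.01, 1 at 2-fold or more, 1 to 4135 with a library left out, and 624 with the crossed block and 1 with the block in the knockout arm alone. The labels state no pairing of the libraries. The deviations of the replicates were correlated at -0.47 across genes between the knockout and its control, which a crossed pairing would give, but the crossed block was chosen for that correlation, so whether the libraries are paired stays open. With the compared libraries only, counts were 3920 for shRNA 1, 4106 for shRNA 2, 3787 for the mean knockdown, 5032 between the hairpins, 5645 between the controls and 53 for the difference of effects. The 8 knockdown-arm libraries, with their smaller spread, gave 4304, 4091, 3872, 5038 and 5462 for the first 5 of these. At an adjusted p below 0.01 the counts were 492, 378, 337, 854, 1012 and 32, and at 2-fold or more 181, 121, 77, 244, 406 and 54, both stricter by construction. With a library left out the ranges were 340 to 397, 235 to 275, 134 to 481, 682 to 799, 879 to 921 and 25 to 3342. With vector as control the counts were 2801 for shRNA 2, 2464 for the mean knockdown and 715 for the difference of effects, and with the mean of both controls 1987 for shRNA 2 and 1582 for the mean knockdown. The difference of effects also gave 234 with DESeq2, 505 with no filter, 60 with the replicate block, 1951 with the crossed block, 71 with the block in the knockout arm alone and 93 after thinning. Genes shared by the knockout and both hairpins numbered 2 with DESeq2, 6 with no filter, 0 with the compared libraries only, 2 with vector, 2 with the mean of both controls, and 1 to 183 with a library left out. The correlation of shRNA 1 and shRNA 2 fold changes was -0.17 with shRNA 1 against scramble and shRNA 2 against vector and 0.042 with the controls exchanged, and that of knockout and knockdown was 0.10 with vector. With library sizes alone the counts stayed within 1.5 times, but 34.7% in place of 46.3% of the shRNA 2 calls were up, and 60.2% in place of 49.5% of the genes differing between the hairpins were higher with shRNA 1. Thinning to the lowest total left the counts other than that of the difference of effects within 1.5 times.

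All but 2 of the reversed genes and lists reversed with vector as control. With shRNA 1 the log2 fold changes became -0.60 for MIR210HG, 0.34 for IL24 and 0.33 for CDKN1A. In the mean knockdown they became -0.66 for MIR210HG, -0.32 for P4HA1, -0.11 for BNIP3L, 1.07 for IL24, 0.55 for FAIM3 and 1.08 for TTC29. The difference of effects became 0.29 for MIR210HG, 0.033 for PPFIA4 and 0.14 for BNIP3L. List medians with shRNA 1 became -0.30 for G1/S and replication, -0.048 for nucleotide synthesis, -0.52 for glycolysis, 0.18 for metalloprotease and plasminogen, 0.057 for antigen presentation, 0.66 for NF-kB, 0.12 for immediate early and MAPK feedback, -0.36 for hypoxia and -0.083 for DNA repair genes. With shRNA 2 they became -0.39 for glycolysis, 0.10 for antigen presentation, -0.29 for hypoxia and 0.056 for ER chaperone genes. In the mean knockdown they became -0.41 for G1/S and replication, -0.15 for nucleotide synthesis, -0.42 for glycolysis, 0.10 for antigen presentation, 0.95 for NF-kB, -0.30 for hypoxia and -0.37 for DNA repair genes. The hypoxia median of the difference of effects became 0.25. In the knockout, with a library left out, the median of glycolysis genes ran from -0.33 to 0.024 and that of ribosomal protein genes from -0.44 to 0.20, both above 0 without replicate 1 of its control.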

Other observations

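The tests between the arms, of the genes called with both hairpins against both controls and of the neighbouring genes were chosen after the values had been seen, while the list tests in the knockdown and the test of the difference were planned.

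The 2 arms differ widely, and doxycycline, arm and any batch coincide, so no source can be named. In the knockout control G1/S and replication genes were higher than in vector and scramble by medians of 2.24 and 2.93, MCM4 by 2.14 and 2.44. Heat shock genes were higher than in vector and scramble by medians of 1.07 and 1.07 (camera adjusted p 0.031 and 0.053 with an estimated correlation). Fibroblast markers were lower by medians of -2.20 and -2.99 and mesenchymal genes by -1.12 and -1.48, with FN1, the fibronectin gene, at -4.00 and -4.88 and COL1A1, a collagen I gene, at -2.07 and -1.96. In total 7087 of 13365 genes differed in the same direction from both controls, and the first principal component held 73.8% of the variance.

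Lists not described so far had the following medians in the mean knockdown against scramble, none of them called by camera: Notch pathway genes 0.21 (2 of 9 up), interferon-stimulated genes -0.13 (1 of 28 down), NRF2 target genes -0.10 (1 of 22 down), amino acid response (ATF4) genes 0.05 (1 of 22 up, 4 down), YAP/TAZ target genes -0.07 (2 of 20 up, 3 down), Wnt target genes -0.02 (3 of 14 up, 2 down), apoptosis regulator genes -0.06 (2 of 23 up, 1 down) and small RNA processing genes 0.02 (2 of 16 up). Adjusted over the list alone these lists had, in the same order, 2, 0, 0, 2, 2, 3, 2 and 2 up and 1, 0, 2, 5, 5, 2, 2 and 0 down. Of 20 epithelial genes 8 passed the filter and were tested, of 23 squamous epithelial markers 4 and of 18 blood and endothelial cell markers 3, while 13 of 14 fibroblast markers and 23 of 23 mesenchymal genes were tested. In the mean knockdown against scramble the medians of the first 3 of these lists were 0.05, -0.17 and -0.19, with 1 epithelial gene down and no other member called (1 epithelial gene and 1 squamous marker down adjusted over the list alone). Against vector, ATF4 genes fell in 13 of 22 and rose in 1 (median -0.56, camera adjusted p 1.2e-12; adjusted p = 0.029 with an estimated correlation; 1 up and 14 down adjusted over the list alone) and YAP/TAZ target genes fell in 8 of 20 and rose in 1 (median -0.28, camera adjusted p 1.2e-06; adjusted p = 0.021 with an estimated correlation; 1 up and 8 down adjusted over the list alone). NRF2 target genes had a median of -0.34 and Notch pathway genes of 0.42 against vector (camera adjusted p 0.0014 and 0.026; adjusted p = 0.10 and adjusted p = 0.16 with an estimated correlation). Among the YAP/TAZ target genes, CYR61 and CTGF, which encode secreted matricellular proteins, fell by 1.08 and 0.81 against vector and by 0.52 and 0.43 against scramble.

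The 31 genes raised by both hairpins against both controls had a median log2 fold change of 0.11 in the knockout, with 20 of the 31 above 0 (camera adjusted p 9.9e-04; adjusted p = 0.10 with an estimated correlation). Of the 39 genes lowered by both, 38 were tested as a set in the knockout and had a median of 0.01. Over these 69 genes, 38 had the same sign in the knockout as in the knockdown, and 22 were called in the test of the difference.

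A stretch of neighbouring genes on chromosome 11 in the GRCh38.p14 order, YAP1, BIRC3, BIRC2 and TMEM123, was expressed at mean log2 CPM of 12.2, 10.4, 11.3 and 12.2, BIRC3 being also in the NF-kB list. In this paragraph CPM were scaled by library total without TMM, and 0.5 was added before the log2. By the second-lowest level among 5 neighbouring protein-coding genes, the stretch ranked first of 18846 runs in 12 of 12 libraries. The gap to the next run apart from it was 1.72 to 3.67 log2 units over the libraries. At both ends the level of the run was that of BIRC3, 9.40 in a vector library and 11.4 in a knockout control library. The gap there follows that gene and not the whole stretch. A gain of copies of this stretch may underlie these levels, as a hypothesis; the stretch was picked for its level and RNA does not separate copies from transcription, so the smallest gap of 1.72 leaves it open.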
